A study of Mus musculus with 16 samples.

How the data were processed

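Total RNA from mouse brain was measured on 16 Affymetrix expression arrays, 4 for each of 4 groups. Arrays of 1 group correlated with r between 0.968 and 0.984 over probe sets, and none were duplicates. The RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The groups were normal brain (control), PDGF-p53 tumours, PDGF-p53-RBPJ tumours and p53-RBPJ tumours, and each array was assigned by its title and source label. The labels number the arrays within a group but do not say that these are separate animals, so p-values measure the spread between these samples. Both sex patterns occurred among the arrays of normal brain, PDGF-p53 and PDGF-p53-RBPJ tumours, so none of these groups came from 1 animal alone. All 4 p53-RBPJ arrays showed 1 pattern. Yet most of 34 neighbouring genes from Sox5 to Resf1 were raised in replicates 3 and 4 alone, with medians of 3.12 and 1.76. This argues against 4 repeats of 1 RNA sample. Whether arrays of 1 pattern in a group came from separate animals stays open, and a part of their spread may be technical.

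The deposited table holds log2 expression values for 35556 probe sets, made by the authors with RMA in the oligo package, per the submitters' processing notes. The versions of both, the array annotation build and any filter are not given in the sources used here. The values run from 1.20 to 14.1 with 0 missing values, as RMA values on the log2 scale do. RMA equalises the distributions of arrays, so a change in the total RNA of a cell cannot be seen. The medians of the control arrays were 6.00, 6.04, 6.00 and 5.99, and those of the PDGF-p53 arrays 6.00, 5.97, 6.05 and 6.00. PDGF-p53-RBPJ arrays had medians of 5.97, 6.04, 5.98 and 6.05, and p53-RBPJ arrays had 5.99, 6.02, 6.03 and 6.06. The values are single-colour, so they have no ratio direction, and medians near 6 leave no sign of centring per gene. Whether a further scaling step was applied after RMA stays unknown, since scanner files were not used here.

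Gene names came from the array's annotation table. It lists 23410 of the probe sets, of which 21789 have 1 gene symbol and 1621 have several, and 12146 probe sets are unnamed here. Symbols of 21701 probe sets matched the reference gene table of assembly GRCm38.p6, which updated 2 symbols, and 88 kept the symbol of the annotation. Only probe sets with 1 symbol were used. Where a gene had several probe sets (1001 genes), the one with the highest mean over the 16 arrays was taken, which left 19936 genes. No coordinates are given because the build of the array annotation is not named. The reference table served for symbols and for which genes are neighbours. Probe sets with several symbols or none were tested apart and stand in the closing section.

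Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust settings). All 16 arrays entered one fit with 12 residual degrees of freedom, to which eBayes added 5.33 prior degrees of freedom. Each of 6 comparisons was tested two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Fold changes are differences of mean log2 values with the standard error (SE) of the fit. Single genes of the engineered pathway were also compared by an exact two-sided permutation test of 4 against 4 arrays, whose smallest p is 0.0286. The median SE of a difference was 0.15 on the log2 scale, and the number of arrays limits the precision. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.

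Gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests and the rule for naming genes. Of 28 lists, 25 with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They cover proliferation, cell cycle inhibitors, p53 targets, Notch core and Notch target genes, the PDGF axis, oligodendrocyte precursors, neural stem cells, neuroblasts, neurons, astrocytes, oligodendrocytes, choroid plexus and ependyma, endothelium, mural cells, microglia, myeloid cells, lymphocytes, MHC class II, interferon response, mesenchymal genes, matrix and epithelial-mesenchymal transition, hypoxia and glycolysis, immediate early genes, and cholesterol synthesis. The erythroid list had 2 measured members and was not tested. Housekeeping genes (12 measured) served for centring and sex genes (4 measured) for the sex pattern. Each list was also tested with a correlation estimated from the data and with fry.

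The rule for naming genes took, among genes past the adjusted threshold with no overlap between the values of both groups, the 12 largest rises and 12 largest falls in 4 main comparisons and 6 of each in the other 2 (PDGF-p53-RBPJ against control and p53-RBPJ against PDGF-p53), leaving out gene models without a proper symbol and small RNAs. It added Pdgfb, Trp53, Rbpj, all Notch targets and PDGF axis genes, and up to 4 members of each other list past the threshold, or the 2 with the smallest p where none passed, and these added genes were not held to the overlap condition. Trp53 was not analysed here. The text names a part of these genes, chosen after their values were seen, with a preference for calls that held when any 1 array was left out.

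The tests were checked on simulated data with the real means and spreads. For p53-RBPJ against PDGF-p53-RBPJ, 22% of changes of 0.5 on the log2 scale, 86% of changes of 1 and 100% of changes of 2 were recovered, with 6 false calls among 185 over 19936 genes. For PDGF-p53-RBPJ against PDGF-p53, the same changes were recovered in 20%, 74% and 100% of cases, with 6 false calls among 178 over 19936 genes. Recovery depends on the number of genes called and is lower where fewer are called. Because the comparisons with normal brain share 4 control arrays, overlaps were set beside 50 simulations of unchanged groups, beside independent lists and beside values with the controls split 2 against 2.

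Alternatives fixed before the data were examined were the mean of a gene's probe sets, every probe set, a filter on dim genes, median centring, housekeeping centring, cyclic loess, eBayes with trend and robust, array weights, a fit of the 2 groups compared, a replicate block and leaving out each array. A term for the sex pattern of each array, read from Xist and Y-linked genes, was added after the data had been seen.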

Results

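The arrays covered normal mouse brain and 3 types of genetically induced brain tumour, with 4 arrays for each group. PDGF-p53 tumours arose in mice with floxed p53 after a retrovirus delivered PDGF-B, a growth factor for glial precursors, together with Cre recombinase. PDGF-p53-RBPJ tumours arose from the same retrovirus in mice in which RBPJ, the DNA-binding effector of Notch signalling, was floxed as well. In p53-RBPJ tumours no retrovirus was used, and a Cre transgene driven by Hes5, a gene of neural stem cells, removed p53 and RBPJ. Tumours were found by a GFP reporter that Cre switches on and dissected from the brain once mice were ill, so a sample can hold host brain as well as tumour cells. The first principal component held 56.9% of the variance. It placed the control arrays between -76.6 and -73.2 and the tumour arrays between -8.8 and 40.3. PDGF-p53 replicate 3 lay nearest to the controls, at -8.8, and its mean over the neuron list was 8.28, against a median of 7.14 in the other 3 arrays of its group. Xist and Y-linked genes showed the female pattern in 2 of 4 control arrays, 1 of 4 PDGF-p53 arrays, 1 of 4 PDGF-p53-RBPJ arrays and 4 of 4 p53-RBPJ arrays.

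The first question was whether the engineered genes and the Notch targets followed the genotype. Rbpj averaged 8.32 ± 0.16 (log2, SD, n = 4) in PDGF-p53 tumours, 7.73 ± 0.15 in PDGF-p53-RBPJ tumours, 7.78 ± 0.12 in p53-RBPJ tumours and 8.01 ± 0.20 in normal brain. Between both PDGF tumour types the Rbpj difference was -0.59 (95% confidence interval -0.85 to -0.32), with no overlap of arrays and an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays allow. Among all genes its adjusted p was 0.269. Between p53-RBPJ and PDGF-p53 tumours Rbpj fell by 0.53 (adjusted p = 0.0191). That call was lost without PDGF-p53 replicate 2 (0.0611) or p53-RBPJ replicate 2 (0.0536), with housekeeping centring (0.0818), with a sex term (0.112), with only the 2 groups in the fit (0.0645) and with the mean of the probe sets (0.103). The Rbpj value was -0.50 and -0.49 without these arrays, -0.39 with housekeeping centring, -0.55 with a sex term, -0.53 with only the 2 groups and -0.34 with the mean of the probe sets. Against normal brain the Rbpj values were -0.28 (adjusted p = 0.101) in PDGF-p53-RBPJ and -0.23 (adjusted p = 0.182) in p53-RBPJ tumours. A probe set can also read exons outside the floxed part, and host cells in the sample keep the gene. Mouse Pdgfb was 0.14 ± 0.15 (log2 difference ± SE, adjusted p = 0.565) from normal brain in PDGF-p53 tumours and 0.13 ± 0.15 (adjusted p = 0.58) in PDGF-p53-RBPJ tumours. In p53-RBPJ tumours Pdgfb was -0.36 from normal brain (adjusted p = 0.0805), -0.49 from PDGF-p53-RBPJ (adjusted p = 0.0962) and -0.50 from PDGF-p53 tumours (adjusted p = 0.0693). Its arrays did not overlap with those of either PDGF type (exact permutation p = 0.0286 for each). The probe set may not read the retroviral PDGF-B sequence, and whether these differences come from the virus was not tested.

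Fabp7, a fatty acid binding protein of radial glia and a Notch target, rose by 2.41 ± 0.17, 2.16 ± 0.17 and 2.06 ± 0.17 (adjusted p = 1.37e-08, 3.76e-08 and 3.7e-08) over normal brain in PDGF-p53, PDGF-p53-RBPJ and p53-RBPJ tumours. Hey1, a Notch-induced repressor, fell by 0.66, 0.73 and 0.96 in the same order (adjusted p = 0.000267, 8.32e-05 and 3.32e-06). Hey2, its relative, rose by 0.94, 1.33 and 1.52 (adjusted p = 0.0419, 0.00469 and 0.00148), with an exact permutation p of 0.0571 and overlapping arrays in PDGF-p53 tumours. Its direct difference from PDGF-p53 tumours did not pass, at 0.39 (adjusted p = 0.98) for PDGF-p53-RBPJ and 0.58 (adjusted p = 0.39) for p53-RBPJ. The Hey2 call in PDGF-p53 tumours was lost without control replicate 1 (0.11), 3 (0.0806) or 4 (0.0692), PDGF-p53 replicate 1 (0.107), 2 (0.112) or 4 (0.0796), PDGF-p53-RBPJ replicate 2 (0.0513) or p53-RBPJ replicate 4 (0.0501), with every probe set (0.07), with trend and robust (0.0602) and with a sex term (0.0675). Hes5, a repressor induced by Notch, fell by 0.47 in PDGF-p53-RBPJ (adjusted p = 0.00576) and 0.33 in p53-RBPJ tumours (adjusted p = 0.0433; permutation p = 0.0571, overlapping arrays) and was at -0.17 in PDGF-p53 tumours (adjusted p = 0.333). Its direct difference from PDGF-p53 tumours did not pass either, at -0.30 (adjusted p = 0.888) and -0.16 (adjusted p = 0.554). The Hes5 call in p53-RBPJ tumours was lost without control replicate 1 (0.0878), 2 (0.0902) or 3 (0.101), PDGF-p53 replicate 1 (0.0525), PDGF-p53-RBPJ replicate 1 (0.0511), 3 (0.0543) or 4 (0.0508) or p53-RBPJ replicate 1 (0.0837), 2 (0.0597) or 3 (0.128), with every probe set (0.0524), housekeeping centring (0.168), only the 2 groups in the fit (0.0576), a replicate block (0.0634) and a sex term (0.122). Hes1, a further Notch-induced repressor, rose by 0.69 ± 0.18 in PDGF-p53 tumours (adjusted p = 0.0076; permutation p = 0.0571, overlapping arrays), and its values were 0.16 (adjusted p = 0.568) and 0.18 (adjusted p = 0.506) in the tumours that lacked RBPJ. The direct Hes1 difference did not pass the test, at -0.53 (adjusted p = 0.785) for PDGF-p53-RBPJ and -0.51 (adjusted p = 0.118) for p53-RBPJ against PDGF-p53. Of the 10 measured Notch targets, 3 rose and 2 fell against normal brain in PDGF-p53 tumours, 2 rose and 2 fell in PDGF-p53-RBPJ tumours and 2 rose and 3 fell in p53-RBPJ tumours. Adjusted over the list alone these counts were 3 and 2, 2 and 3, and 2 and 3, and the list did not pass in any of them (camera adjusted p = 0.725, 0.966 and 0.948). Of the 10, 0 passed between both PDGF tumour types, over all genes and adjusted over the list alone, and 7 of 10 had a negative value (camera adjusted p = 0.0511). Pdgfra, the receptor of PDGF ligands on glial precursors, rose by 3.53 ± 0.33, 3.26 ± 0.33 and 3.87 ± 0.33 in the 3 tumour types (adjusted p = 3.21e-07, 6.1e-07 and 5.57e-08), including the type without the virus. The Fabp7, Hey1 and Pdgfra calls and the other Hey2 and Hes5 calls had no overlap and a permutation p of 0.0286. The Pdgfra value in p53-RBPJ replicate 3 was 10.77, against a median of 12.78 in the other 3 arrays.

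**Figure D1:**
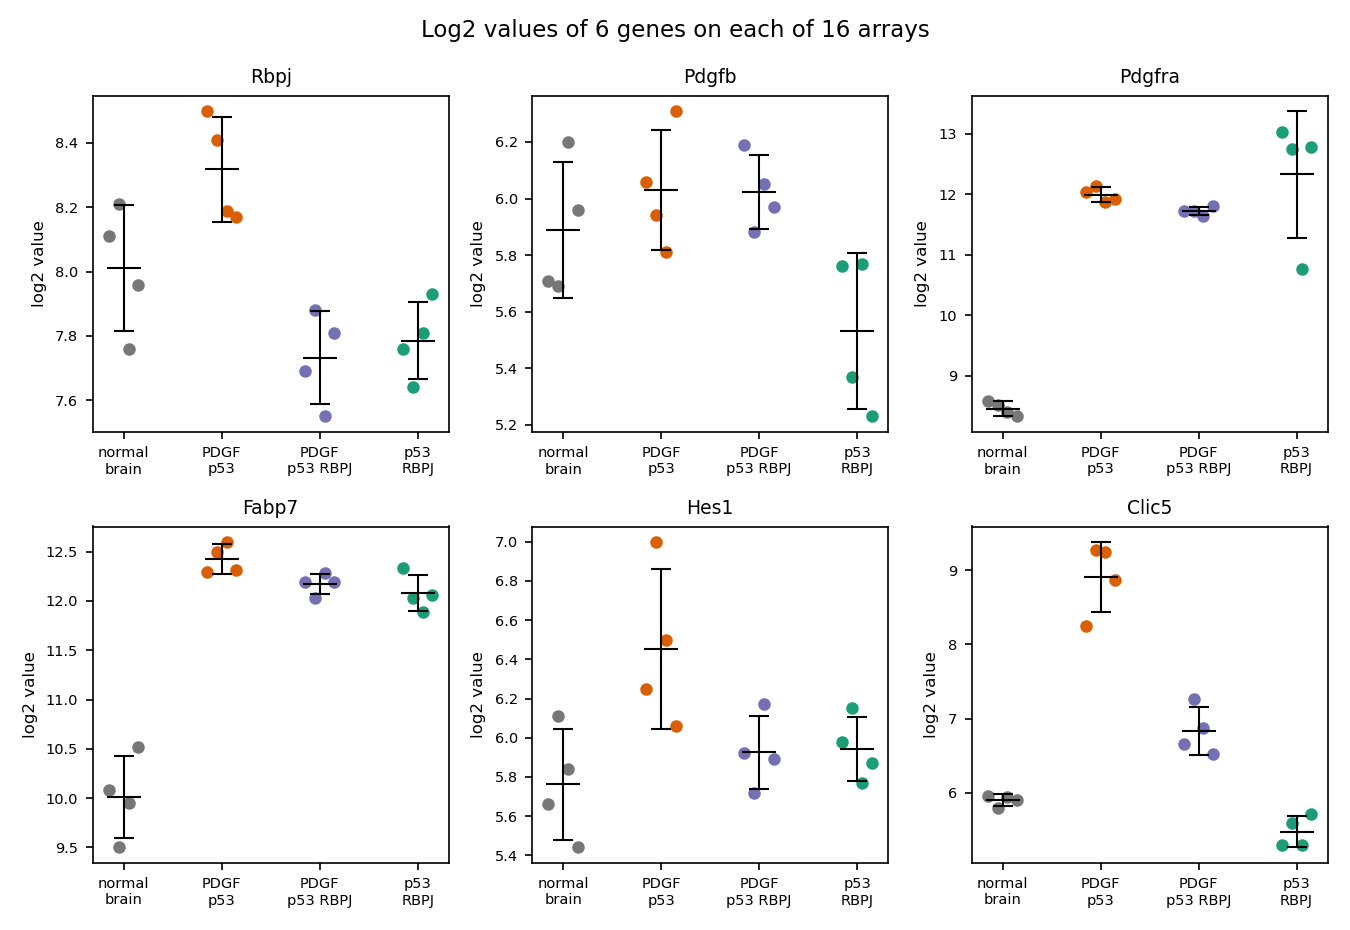
Log2 values of Rbpj, Pdgfb, Pdgfra, Fabp7, Hes1 and Clic5 (vertical axis) on each array of the 4 groups (horizontal axis), with points for arrays, long bars for group means and short bars for 1 SD. Clic5 averaged 8.90 in PDGF-p53, 6.83 in PDGF-p53-RBPJ and 5.48 in p53-RBPJ tumours and 5.90 in normal brain.

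The comparison of PDGF-p53 tumours with normal brain asked what the PDGF-driven tumour expressed. Genes of cell division rose most. Bub1, a spindle checkpoint kinase, rose by 4.92 ± 0.24 on the log2 scale (30.2-fold, 4 arrays against 4), and Top2a, the topoisomerase of dividing cells, by 4.80 ± 0.19 (27.8-fold). With the mean of its probe sets the Top2a value was 2.79 here, 2.97 in PDGF-p53-RBPJ and 3.35 in p53-RBPJ tumours. Genes of oligodendrocyte precursors rose too, among them the transcription factor Sox6 (2.85 ± 0.12) and the proteoglycan Vcan (2.76 ± 0.22). Neuronal genes fell, with Calb1, a calcium-binding protein, lower by 16.7-fold and with a log2 difference of -4.06 ± 0.41. limma called 6208 of 19936 genes, 2703 higher and 3505 lower, of which 2062 changed at least 2-fold.

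Among proliferation genes 40 of 41 measured members rose, over all genes and adjusted over the list alone (median 2.41, camera adjusted p = 7.58e-45). Further examples were Mki67, the Ki-67 antigen (4.07 ± 0.18), and Ccnd1, a cyclin of early cell cycle (3.77 ± 0.19). Of the oligodendrocyte precursor list 19 of 20 members rose, also 19 adjusted over the list alone (median 1.88, camera adjusted p = 4.21e-20). Both lists held with an estimated correlation (adjusted p = 0.0328 and 0.00819). Of the cell cycle inhibitors 4 of 9 rose, 5 adjusted over the list alone, with 1 lower there (median 0.89, camera adjusted p = 0.00237; adjusted p = 0.0577 with an estimated correlation). Cdkn2c, an inhibitor of CDK4 and CDK6, rose by 2.85 ± 0.18 and Rbl1, a relative of the retinoblastoma protein, by 2.27 ± 0.13.

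Neuron genes fell in 29 of 30 cases, 29 adjusted over the list alone (median -2.37, camera adjusted p = 6.65e-19; adjusted p = 0.132 with an estimated correlation). The NMDA receptor subunit Grin2b was at -3.30 ± 0.38, the neurofilament Nefl at -3.25 ± 0.39 and the interneuron marker Pvalb at -3.44 ± 0.40. Astrocyte genes fell in 14 of 19 cases and rose in 1, the same counts adjusted over the list alone (median -1.22, camera adjusted p = 1.32e-05; adjusted p = 0.33 with an estimated correlation). The gap junction genes Gjb6 and Gja1 were at -2.71 ± 0.27 and -2.37 ± 0.38. Mature oligodendrocyte genes fell in 8 of 17 cases, 8 adjusted over the list alone, with Aspa at -2.58 ± 0.56 and the myelin gene Mobp at -2.45 ± 0.56 (list median -0.78, camera adjusted p = 0.0188; adjusted p = 0.787 with an estimated correlation). Both genes overlapped with normal brain in PDGF-p53 replicate 3, at 7.72 for Aspa and 10.82 for Mobp. The oligodendrocyte call was lost without control replicate 4 (median -0.48, adjusted p = 0.166), and without dim genes the median was -1.28. Choroid plexus and ependymal genes fell in 5 of 14 cases, 5 adjusted over the list alone (median -0.35, camera adjusted p = 0.025; adjusted p = 0.527 with an estimated correlation), and that call too was lost without control replicate 4 (0.0816).

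Mesenchymal genes rose in 8 of 21 cases, 8 adjusted over the list alone (median 0.52, camera adjusted p = 0.00124; adjusted p = 0.482 with an estimated correlation). The intermediate filament Vim rose by 1.91 ± 0.20 and the transcription factor Stat3 by 1.35 ± 0.20. Interferon response genes rose in 6 of 17 cases, 12 adjusted over the list alone, with Ifit2 up by 1.43 ± 0.25 (list median 1.43, camera adjusted p = 0.000196; adjusted p = 0.702 with an estimated correlation). The mean of that list ranged from 6.74 to 8.76 over the PDGF-p53 arrays. Myeloid genes rose in 8 of 29 cases and fell in 1, with 9 and 1 adjusted over the list alone (median 0.47, camera adjusted p = 0.0046; adjusted p = 0.702 with an estimated correlation). The chemokine Ccl2 rose by 1.84 ± 0.27 and the lysozyme gene Lyz2 by 1.75 ± 0.48, with overlap, as PDGF-p53 replicate 3 was at 8.09 and control replicate 1 at 8.49. Notch core genes rose in 9 of 24 cases and fell in 4, with 10 and 4 adjusted over the list alone (median 0.19, camera adjusted p = 0.0419; adjusted p = 0.33 with an estimated correlation). The ligand Jag1 rose by 1.47 ± 0.17 and the receptor Notch1 by 1.01 ± 0.15. The Notch core call was lost without control replicate 3 (0.0517), control replicate 4 (0.0795), PDGF-p53 replicate 4 (0.0676), PDGF-p53-RBPJ replicate 4 (0.0513) or p53-RBPJ replicate 4 (0.0504), with the mean of probe sets (0.0642), without dim genes (0.0796), with array weights (0.0527) and with a sex term (0.0506). Without PDGF-p53 replicate 3 the mesenchymal median was 0.91, and without PDGF-p53 replicate 4 the myeloid median was 0.28. Without control replicate 4 the Notch core median was 0.12, as with the mean of probe sets, and it was 0.11 with housekeeping centring.

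Other lists did not pass camera. Their adjusted p was 0.834 for cholesterol synthesis, 0.371 for matrix and epithelial-mesenchymal transition, 0.378 for endothelium, 0.725 for hypoxia and glycolysis, 0.47 for immediate early genes, 0.429 for lymphocytes, 0.0835 for MHC class II and 0.725 for microglia. For mural cells, Notch targets and the PDGF axis it was 0.725 each, for neuroblasts and neural stem cells 0.503 each, and for p53 targets 0.847. Within the neural stem list 4 of 16 members rose and 2 fell over all genes, and 4 rose and 3 fell adjusted over the list alone, with a median of -0.20 and a mean of 0.27. Nes, an intermediate filament of stem cells, rose by 2.50 ± 0.24 and the transcription factor Sox2 by 1.40 ± 0.19. Median, mean and test also differed in sign for cholesterol synthesis, Notch targets, p53 targets and the PDGF axis.

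**Figure D2:**
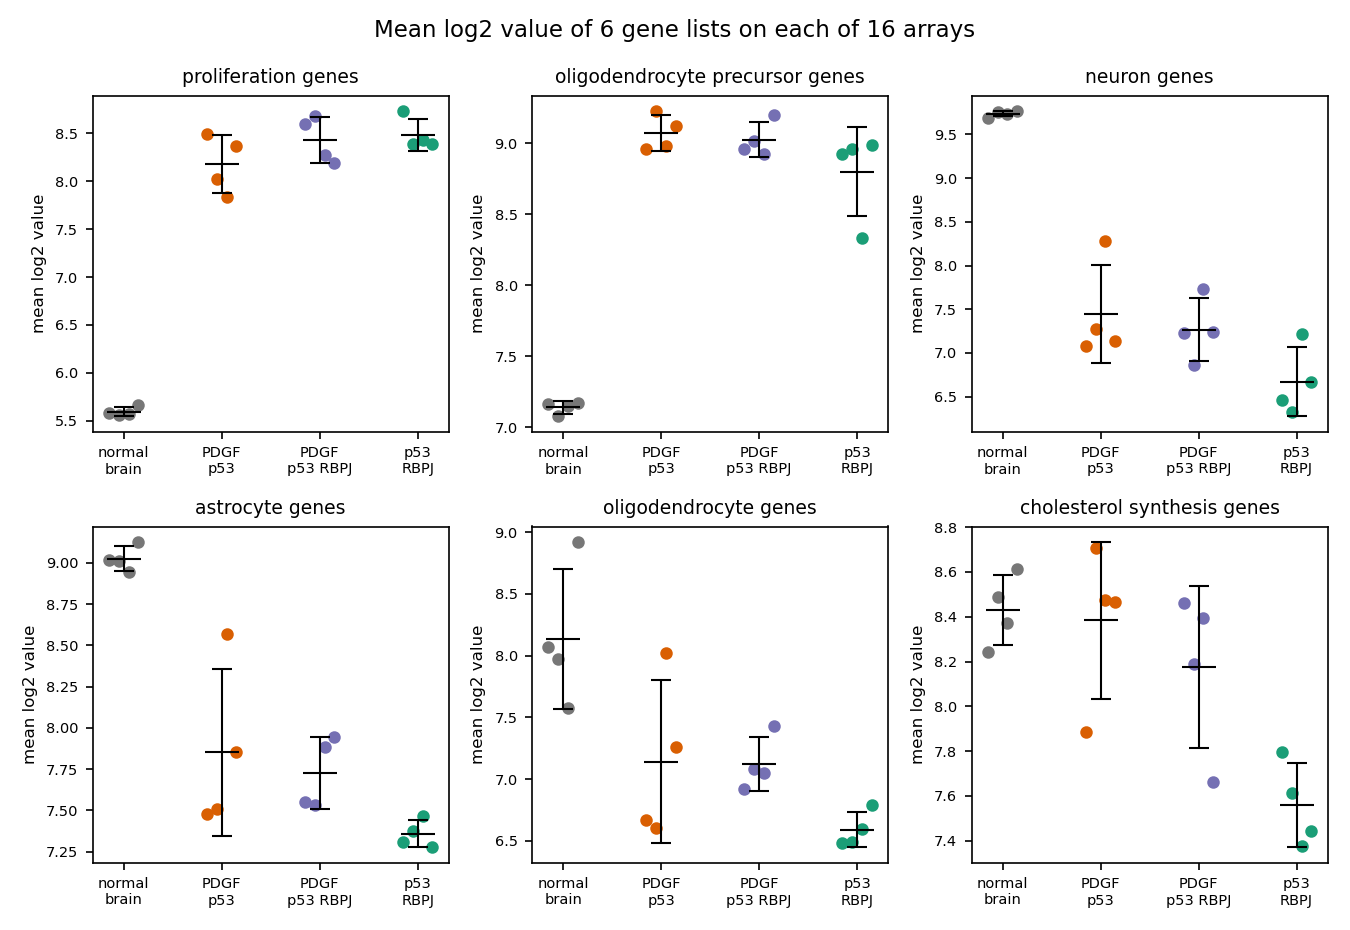
Mean log2 value of the measured genes of 6 lists (proliferation, oligodendrocyte precursor, neuron, astrocyte, oligodendrocyte and cholesterol synthesis; vertical axis) on each array of the 4 groups (horizontal axis), with points for arrays, long bars for group means and short bars for 1 SD. The 4 control arrays sit between 9.69 and 9.76 for neuron genes and between 5.56 and 5.67 for proliferation genes, while p53-RBPJ arrays sit between 6.32 and 7.22 and between 8.38 and 8.74.

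In p53-RBPJ tumours, compared with normal brain to describe the tumour made without PDGF-B, genes of cell division again rose most and neuronal genes fell most. Top2a rose by 5.24 ± 0.19 (37.9-fold), Bub1 by 5.05 ± 0.24 and Kif4, a mitotic kinesin, by 4.37 ± 0.15 (4 arrays against 4). Stmn2, a regulator of microtubules in neurons, was at -5.27 ± 0.54 (38.7-fold lower), the synaptic vesicle gene Sv2b at -5.22 ± 0.46 and the membrane trafficking gene Mal2 at -5.09 ± 0.45. Genes of cholesterol synthesis fell, among them Hmgcs1, an early enzyme of the pathway (-1.72 ± 0.26), and Sc5d, a late one (-1.60 ± 0.19). limma called 7330 genes, 3263 higher and 4067 lower, of which 2697 changed at least 2-fold.

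Proliferation genes rose in 40 of 41 cases and oligodendrocyte precursor genes in 17 of 20, with the same counts adjusted over the list alone (camera adjusted p = 1e-39 and 1.18e-12; both 0.0495 as adjusted p with an estimated correlation). All 30 neuron genes fell, with a median of -3.07, and 30 did so adjusted over the list alone (camera adjusted p = 1.47e-21; adjusted p = 0.0912 with an estimated correlation). Astrocyte genes fell in 15 of 19 cases, 16 adjusted over the list alone (median -1.80, camera adjusted p = 6.39e-08; adjusted p = 0.195 with an estimated correlation), including the glutamate transporter Slc1a2 (-3.29 ± 0.32). Oligodendrocyte genes fell in 10 of 17 cases, 10 adjusted over the list alone (median -1.67, camera adjusted p = 0.00166; adjusted p = 0.538 with an estimated correlation), with Mobp at -3.94 ± 0.56. Cholesterol genes fell in 10 of 14 cases, 10 adjusted over the list alone (median -0.82, camera adjusted p = 0.00156; adjusted p = 0.538 with an estimated correlation). Interferon genes rose in 5 of 17 cases, 5 adjusted over the list alone, and the mean of that list spread from 6.40 to 9.11 over the 4 tumour arrays (median 1.22, camera adjusted p = 0.00336; adjusted p = 0.684 with an estimated correlation). Without p53-RBPJ replicate 2 the interferon median was 0.78.

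Cell cycle inhibitors rose in 6 of 9 cases and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 0.00599; adjusted p = 0.0912 with an estimated correlation). Choroid plexus genes fell in 7 of 14 cases, 7 adjusted over the list alone (camera adjusted p = 0.0271; adjusted p = 0.538 with an estimated correlation), a call lost without control replicate 4 (0.0669). Mesenchymal genes rose in 7 of 21 cases and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 0.0322; adjusted p = 0.608 with an estimated correlation). That call was lost without control replicate 3 (0.0633), without p53-RBPJ replicate 2 (median 0.28, adjusted p = 0.0842), without dim genes (0.147) and with a sex term (0.0712). Of the myeloid list 8 of 29 members rose and 4 fell, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.184). Its member Gpnmb, a glycoprotein of lysosomes in phagocytes, rose by 3.58 ± 0.50 and Lyz2 by 2.76 ± 0.48. Siglech, a receptor of resident microglia, was at -1.68 ± 0.21, and 6 of 10 microglia genes fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.0908).

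PDGF-p53-RBPJ tumours, compared with normal brain to describe the virus-induced tumour without RBPJ, showed the same leading genes of cell division. Top2a and Bub1 rose by 5.03 ± 0.19 and 5.03 ± 0.24 (32.8-fold and 32.7-fold, 4 arrays against 4), and Mki67 by 4.35 ± 0.18. Calb1 was at -4.12 ± 0.41, Sphkap, an anchor protein for protein kinase A, at -3.84 ± 0.29 and the neuronal surface glycoprotein Thy1 at -3.57 ± 0.32. Lgals1, a galectin of the mesenchymal list, rose by 2.32 ± 0.24. limma called 6702 genes, 3126 higher and 3576 lower, of which 2245 changed at least 2-fold. Proliferation genes rose in 40 of 41 cases, precursor genes in 19 of 20 and cell cycle inhibitors in 5 of 9, or 40, 20 and 6 adjusted over the list alone. These 3 lists held with an estimated correlation (adjusted p = 0.0293, 0.0147 and 0.0293).

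Neuron genes fell in 29 of 30 cases and astrocyte genes in 14 of 19 with 1 higher, the same counts adjusted over the list alone (camera adjusted p = 6.89e-20 and 4.05e-06; adjusted p = 0.113 and 0.336 with an estimated correlation). Mesenchymal genes rose in 12 of 21 cases, 12 adjusted over the list alone (median 1.02, camera adjusted p = 0.000117; adjusted p = 0.356 with an estimated correlation). Choroid plexus genes fell in 7 of 14 cases, 7 adjusted over the list alone, and myeloid genes rose in 9 of 29 with 2 lower, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00966 and 0.0152; adjusted p = 0.422 and 0.829 with an estimated correlation). Oligodendrocyte genes fell in 8 of 17 cases, 9 adjusted over the list alone with 1 higher there (camera adjusted p = 0.0194; adjusted p = 0.829 with an estimated correlation). The oligodendrocyte call was lost without control replicate 4 (0.196) or PDGF-p53-RBPJ replicate 2 (0.0532). Without control replicate 4 the oligodendrocyte median moved from -0.97 to -0.60 and the choroid plexus median from -0.58 to -0.38. Interferon genes rose in 3 of 17 cases, 1 adjusted over the list alone (camera adjusted p = 0.00966; adjusted p = 0.829 with an estimated correlation), a call lost without PDGF-p53-RBPJ replicate 1 (0.0726) or dim genes (0.0984).

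Across the 3 tumour types, 4836 genes changed the same way against normal brain, 2026 higher and 2810 lower. Top2a, Bub1, Mki67, Pdgfra, Sox6 and Vcan were higher in each, and Calb1, Sphkap, Gjb6, Gja1, Aspa and Mobp were lower in each. Unchanged groups were simulated as independent noise around the control means, with simulated controls shared, and gave 0 such genes in 50 simulations. As no gene differs there, a count near 0 was fixed in advance and says little about shared controls. Independent lists would share 69 higher and 128 lower. PDGF-p53 and PDGF-p53-RBPJ tumours shared 2392 higher and 3015 lower genes, against 424 and 629 for independent lists and 0 in the simulation. PDGF-p53 and p53-RBPJ tumours shared 2139 and 3035, against 442 and 715, and PDGF-p53-RBPJ and p53-RBPJ tumours shared 2464 and 3076, against 512 and 730, with 0 in the simulation for each pair. With the controls split 2 against 2 the shared genes were 1540 higher and 2083 lower, 1406 and 2151, and 1664 and 2230. Fold changes correlated across genes, which are not independent replicates, with r of 0.961, 0.898 and 0.912, where simulated unchanged groups gave 0.499, 0.501 and 0.501. With split controls r was 0.904, 0.846 and 0.858. The covariances of 0.463, 0.482 and 0.516 exceeded the simulated 0.017 by 0.446, 0.465 and 0.499.

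RBPJ loss within the PDGF tumours was addressed by PDGF-p53-RBPJ against PDGF-p53 tumours, where limma called 4 genes. In simulated data, where 178 genes were called, this comparison recovered 20% of changes of 0.5 and 74% of changes of 1 (log2). The adjusted threshold is stricter where fewer genes are called, so these shares overstate the recovery with 4 calls. Changes of 1 and smaller may have been missed. Clic5, an intracellular chloride channel family member, was 4.21-fold lower without RBPJ, with a log2 difference of -2.07 ± 0.20 (adjusted p = 0.000145, 4 arrays against 4) and no overlap between arrays. Clic5 averaged 8.90 ± 0.47 (SD, n = 4) in PDGF-p53 and 6.83 ± 0.32 in PDGF-p53-RBPJ tumours, against 5.90 ± 0.08 in normal brain. Clic5 also differed between both types that lack RBPJ. It was lower by 1.35 ± 0.20 in p53-RBPJ than in PDGF-p53-RBPJ tumours (limma adjusted p = 0.00205), with no overlap. Hspa1l, a heat shock protein, rose by 1.01 ± 0.15 (adjusted p = 0.0305). Snora73b and Snora33, small nucleolar RNAs that lie outside the naming rule and were chosen after their values were seen, rose by 1.36 ± 0.17 (adjusted p = 0.00305) and 1.01 ± 0.16 (adjusted p = 0.0309). These 4 genes were all that limma called, 3 higher and 1 lower of 19936, and 1033 genes had an unadjusted p under 0.05 where 997 would by chance. Clic5 and Snora73b kept their calls in every alternative setting. Hspa1l lost its call in 14 of 27 settings and Snora33 in 18. For Hspa1l these were leaving out PDGF-p53 replicate 1 (0.0598), 2 (0.0819), 3 (0.0644) or 4 (0.0571), PDGF-p53-RBPJ replicate 1 (0.0559), 2 (0.198), 3 (0.0592) or 4 (0.112), control replicate 2 (0.0575) or p53-RBPJ replicate 3 (0.0511). The others were every probe set (0.0989), housekeeping centring (0.0557), only the 2 groups in the fit (0.0742) and a replicate block (0.085). For Snora33 they were leaving out PDGF-p53 replicate 2 (0.131) or 3 (0.12), PDGF-p53-RBPJ replicate 1 (0.0597), 2 (0.207), 3 (0.0807) or 4 (0.112), control replicate 1 (0.0601), 2 (0.0595) or 3 (0.057), or p53-RBPJ replicate 1 (0.055), 3 (0.0515) or 4 (0.0545). The others were every probe set (0.0989), housekeeping centring (0.0654), cyclic loess (0.0598), array weights (0.0566), only the 2 groups in the fit (0.198) and a replicate block (0.085). The gene count was 7 without PDGF-p53 replicate 4. It was 2 without PDGF-p53 replicate 2, any 1 array of the PDGF-p53-RBPJ group, control replicate 2 or p53-RBPJ replicate 3, and also with every probe set, housekeeping centring or a replicate block.

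No member of any list passed over all genes between both PDGF tumour types, while camera called 7 lists for small shifts. Proliferation genes were higher, with 40 of 41 values above 0 and a median of 0.26 (camera adjusted p = 1.33e-07; adjusted p = 0.621 with an estimated correlation), and mesenchymal genes were higher by a median of 0.15, with 1 of 21 past the threshold adjusted over the list alone (camera adjusted p = 0.0183; adjusted p = 0.723 with an estimated correlation). Neuron genes had a median of -0.19 (camera adjusted p = 0.00318), cholesterol genes -0.18 (0.00318), neural stem genes -0.19 (0.0183), interferon genes -0.33 (0.0175) and lymphocyte genes -0.28 (0.0153). With an estimated correlation the adjusted p of these 5 lists was 0.723, 0.723, 0.525, 0.726 and 0.621. Adjusted over the list alone, 0 members passed in these lists and in the proliferation list. None of the 7 held with fry. The proliferation call held with each array left out, with medians of 0.15 without PDGF-p53 replicate 3, 0.15 without PDGF-p53-RBPJ replicate 2 and 0.17 with array weights. The other 6 calls did not hold.

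Neuron genes lost their call without PDGF-p53 replicate 3 (median -0.01, adjusted p = 0.645), where the camera direction turned, without PDGF-p53-RBPJ replicate 2 (median -0.055, adjusted p = 0.585) and with array weights (median -0.037, adjusted p = 0.918). Their median was -0.30 without PDGF-p53-RBPJ replicate 3. Cholesterol genes lost theirs without PDGF-p53 replicate 2 (0.113) or PDGF-p53-RBPJ replicate 4 (0.492) and with array weights (0.639), with medians of -0.09, 0.00 and 0.01. The cholesterol median was -0.41, -0.30 and -0.30 without PDGF-p53 replicate 1 and PDGF-p53-RBPJ replicates 1 and 3. Interferon genes lost their call without PDGF-p53 replicate 4 (median 0.05, adjusted p = 0.874), PDGF-p53-RBPJ replicate 2 (-0.18, 0.132) or PDGF-p53-RBPJ replicate 3 (-0.09, 0.512). Their median was -0.60, -0.59 and -0.53 without PDGF-p53 replicate 2 and PDGF-p53-RBPJ replicates 1 and 4. Lymphocyte genes lost theirs without PDGF-p53 replicate 1 (0.101) or 4 (median -0.06, adjusted p = 0.307). Mesenchymal genes lost theirs without PDGF-p53 replicate 3 (median 0.07, adjusted p = 0.645), PDGF-p53-RBPJ replicate 1 (0.26, 0.129) or PDGF-p53-RBPJ replicate 3 (0.233). The mesenchymal median was 0.27 and 0.26 without PDGF-p53 replicates 1 and 4, 0.25 without dim genes and 0.23 with array weights. Neural stem genes lost their call without PDGF-p53 replicate 3 (median -0.10, adjusted p = 0.0766), PDGF-p53 replicate 4 (0.0995) or PDGF-p53-RBPJ replicate 4 (0.0788) and with array weights (0.0526).

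Tumours that lacked RBPJ with and without PDGF-B were compared as p53-RBPJ against PDGF-p53-RBPJ, which also differ in how the tumour was induced. Pstpip2, an adaptor protein of the actin cytoskeleton, fell by 3.04 ± 0.43 (8.21-fold, adjusted p = 0.00147, 4 arrays against 4). Itga8, an integrin subunit, fell by 2.89 ± 0.43 (adjusted p = 0.00206), and Gng3, a neuronal G protein subunit, by 2.76 ± 0.35 (adjusted p = 0.00065). Enpp6, a phosphodiesterase of newly forming oligodendrocytes, fell by 2.33 ± 0.35 (adjusted p = 0.00219). The transcription factors Foxd1 and Hoxa5 rose by 2.27 ± 0.32 and 1.96 ± 0.30 (adjusted p = 0.00147 and 0.00279), the retinoid carrier Rlbp1 by 1.80 ± 0.25 (adjusted p = 0.00147) and the glutathione transferase Mgst1 by 1.76 ± 0.22 (adjusted p = 0.00065). Mgst1 in p53-RBPJ replicate 3 was 8.77, against a median of 7.58 in the other 3 arrays. Kit, a receptor tyrosine kinase, rose by 2.40 ± 0.46 (adjusted p = 0.00987), with 11.09, 10.63 and 10.94 in p53-RBPJ replicates 1, 2 and 4 and 8.27 in replicate 3.

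limma called 651 genes here, 127 higher (19.5%) and 524 lower, of which 220 changed at least 2-fold. With housekeeping centring 61.5% of the calls were higher, and the median of all genes was 0.142 in that setting. Neuron genes fell in 5 of 30 cases, 7 adjusted over the list alone (median -0.64, camera adjusted p = 3.79e-06; adjusted p = 0.616 with an estimated correlation), with the kinase subunit Camk2b at -1.39 ± 0.17 (adjusted p = 0.00065). Cholesterol genes fell in 3 of 14 cases, 11 adjusted over the list alone (median -0.67, camera adjusted p = 2.45e-07; adjusted p = 0.616 with an estimated correlation). Astrocyte genes fell in 2 of 19 cases, 3 adjusted over the list alone (median -0.29, camera adjusted p = 0.00801; adjusted p = 0.616 with an estimated correlation), the water channel Aqp4 by 1.47 ± 0.27 and the acyl-CoA synthetase Acsbg1 by 1.08 ± 0.18 (adjusted p = 0.00862 and 0.00386). The astrocyte call was lost without PDGF-p53-RBPJ replicate 4 (0.0851) and without dim genes (0.0675). Without PDGF-p53-RBPJ replicate 3 the neuron median was -0.39. Microglia genes fell in 0 of 10 cases, 4 adjusted over the list alone (median -0.50, camera adjusted p = 0.0014; adjusted p = 0.616 with an estimated correlation), and mesenchymal genes in 3 of 21, 4 adjusted over the list alone (median -0.38, camera adjusted p = 0.00801; adjusted p = 0.616 with an estimated correlation). Tnr, a matrix glycoprotein of the precursor list, fell by 2.16 ± 0.35 (adjusted p = 0.0036), while that list did not pass (camera adjusted p = 0.158).

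Camera also called oligodendrocyte genes (median -0.35, adjusted p = 0.0201; 0 fell over all genes and 2 adjusted over the list alone), hypoxia and glycolysis genes (median -0.27, 0.0394; 1 and 2 fell) and immediate early genes (median -0.33, 0.0394; 0 and 0 fell). With an estimated correlation the adjusted p of these 3 lists was 0.616, 0.64 and 0.616. The oligodendrocyte call was lost without PDGF-p53-RBPJ replicate 4 (median -0.22, adjusted p = 0.14) or p53-RBPJ replicate 1 (0.0645) and without dim genes (median -0.603, adjusted p = 0.0594). The hypoxia call was lost without PDGF-p53-RBPJ replicate 1 (median -0.162, adjusted p = 0.12), 2 (-0.127, 0.0892) or 3 (-0.22, 0.0516) or p53-RBPJ replicate 4 (-0.117, 0.471) and without dim genes (0.0867). The immediate early call was lost without PDGF-p53-RBPJ replicate 3 (0.138) or 4 (0.124) or p53-RBPJ replicate 1 (0.152) or 4 (0.0735) and without dim genes (0.16). With housekeeping centring the medians were -0.14 for astrocyte, -0.23 for mesenchymal, -0.20 for oligodendrocyte, -0.12 for hypoxia and -0.18 for immediate early genes. None of the 8 called lists held with fry. All 4 p53-RBPJ arrays had the female pattern and 3 of 4 PDGF-p53-RBPJ arrays the male one, and with a sex term 61 genes were called. Array weights gave 1198, every probe set 351 and only the 2 groups in the fit 395. Of 50 calls named by the rule in this comparison 11 remained with that term. Of the genes printed here, which were chosen after their values were seen, Pstpip2, Itga8, Gng3, Enpp6, Foxd1, Hoxa5, Rlbp1, Mgst1, Camk2b and Acsbg1 kept their calls with that term, while Kit (2.56, adjusted p = 0.0692), Tnr (-1.88, adjusted p = 0.0675) and Aqp4 (-1.36, adjusted p = 0.1) did not, against 2.40, -2.16 and -1.47 without it. The count also fell to 176 without PDGF-p53-RBPJ replicate 3, 238 without replicate 1 and 313 without replicate 2 of that group, and to 362 and 396 without p53-RBPJ replicates 3 and 4.

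Between p53-RBPJ and PDGF-p53 tumours, which differ in PDGF-B, RBPJ and induction, Sycp1, a protein of the meiotic synaptonemal complex, rose by 3.17 ± 0.38 (log2 ± SE, adjusted p = 0.000289, 4 arrays against 4). Itga8 fell by 3.59 ± 0.43 (adjusted p = 0.000289) and Clic5 by 3.42 ± 0.20 (10.7-fold, adjusted p = 5.17e-08). Pstpip2 and Gng3 fell by 2.88 ± 0.43 and 2.81 ± 0.35 (adjusted p = 0.00145 and 0.000353), and Gpc5, a glypican, by 2.52 ± 0.41 (adjusted p = 0.00232). Foxd1 rose by 2.16 ± 0.32 and Rlbp1 by 1.87 ± 0.25 (adjusted p = 0.00145 and 0.00059). limma called 1105 genes, 385 higher (34.8%) and 720 lower, of which 305 changed at least 2-fold. With housekeeping centring 72.6% of the calls were higher, and the median of all genes was 0.156 in that setting.

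Cholesterol genes fell in 7 of 14 cases, 13 adjusted over the list alone (median -0.98, camera adjusted p = 1.46e-11; adjusted p = 0.566 with an estimated correlation), with Sc5d at -1.14 ± 0.19 (adjusted p = 0.0024). Neuron genes fell in 8 of 30 cases, 13 adjusted over the list alone (median -0.83, camera adjusted p = 6.6e-11; adjusted p = 0.566 with an estimated correlation), with Camk2b at -1.48 ± 0.17 (adjusted p = 0.000289). Astrocyte genes fell in 4 of 19 cases, 6 adjusted over the list alone (median -0.39, camera adjusted p = 0.000206; adjusted p = 0.605 with an estimated correlation), with Acsbg1 at -1.11 ± 0.18 (adjusted p = 0.002). Microglia genes fell in 0 of 10 cases, 4 adjusted over the list alone (median -0.51, camera adjusted p = 0.00412; adjusted p = 0.566 with an estimated correlation). Proliferation genes rose in 4 of 41 cases, 5 adjusted over the list alone (median 0.29, camera adjusted p = 1.22e-06; adjusted p = 0.605 with an estimated correlation). Camera called 3 further lists. Oligodendrocyte genes had a median of -0.34 (0.0152; 0 fell over all genes and adjusted over the list alone; adjusted p = 0.605 with an estimated correlation), a call lost without PDGF-p53 replicate 3 (0.173) or 4 (0.0501). Hypoxia genes had a median of -0.35 (0.0373; 2 fell by both counts; adjusted p = 0.647 with an estimated correlation), a call lost without PDGF-p53 replicate 2 (median -0.26, adjusted p = 0.109) or 4 (-0.045, 0.411) or p53-RBPJ replicate 4 (-0.085, 0.395), with median centring (0.0565), with cyclic loess (0.0848) and without dim genes (0.0893). Precursor genes had a median of -0.14 (0.0329; 4 fell, 5 adjusted over the list alone with 1 higher there; adjusted p = 0.605 with an estimated correlation), which turned to 0.01 with housekeeping centring. The precursor call was lost without PDGF-p53 replicate 2 (median -0.064, adjusted p = 0.0962) or 4 (-0.16, 0.054) or p53-RBPJ replicate 3 (-0.081, 0.179), with cyclic loess (0.0848) and without dim genes (0.149). Without PDGF-p53 replicate 3 the neuron median was -0.44, the proliferation median 0.19, the hypoxia median -0.53 and the oligodendrocyte median -0.09. The oligodendrocyte median was -0.58 and -0.56 without PDGF-p53 replicates 1 and 2 and -0.82 without dim genes. The precursor median was -0.25 without p53-RBPJ replicate 2 and -0.075 with array weights. With housekeeping centring the astrocyte, hypoxia and oligodendrocyte medians were -0.24, -0.20 and -0.20. Of the 8 called lists only the cholesterol list held with fry (0.0297). Of 51 calls named by the rule here 16 remained with a sex term. The gene count fell to 183 with that term, to 289 with only the 2 groups in the fit, and to 553, 702 and 727 without PDGF-p53 replicate 2, PDGF-p53 replicate 3 and p53-RBPJ replicate 3.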

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

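The tests on splits of the arrays and the additive sex term were chosen only after the results were seen, while the tests on sex in normal brain and on normal brain tissue were set before.

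Single arrays stood apart from the other 3 of their group in 35 of 420 sets of values tested, and chance gives about 1 in 20, or 21. Over all named sets of values, 83 of 1156 did. The sets share arrays and are not independent, so the number given by chance is a rough guide. In p53-RBPJ replicate 1, Bub1 was 9.59 against a median of 8.75 in the others, Pdgfa 10.7 against 7.18, the PDGF axis list 8 against 6.92 and the proliferation list 8.74 against 8.39. In p53-RBPJ replicate 3, Calb1 was 5.26 against 4.01, Gja1 7.84 against 6.55, Pdgfra 10.77 against 12.78, Kit 8.27 against 10.94, Mgst1 8.77 against 7.58 and the precursor list 8.33 against 8.96. In p53-RBPJ replicate 4, Nes was 6.84 against 6.61 and the hypoxia list 7.60 against 8.19. In PDGF-p53 replicate 3, Sphkap was 6.63 against 5.48, Grin2b 7.65 against 5.79, Aspa 7.72 against 4.74 and the neuron list 8.28 against 7.14. Elsewhere among PDGF-p53 arrays, Hey1 was 7.89 against 7.45 in replicate 2, Heyl 6.57 against 6.05 and Zeb1 10.52 against 11.12 in replicate 1, and Pdgfd 5 against 4.60 and Hspa1l 5.13 against 5.58 in replicate 4. In PDGF-p53-RBPJ replicate 4, Vim was 11.3 against 11.79, Hmgcs1 8.34 against 9.53, Gng3 9.51 against 10.25 and the myeloid list 6.94 against 7.02. Grin2b was 6.85 against 5.80 in PDGF-p53-RBPJ replicate 3, and Slco1a4 4.81 against 5.60 in replicate 1. In control replicate 4, Top2a was 5.94 against 5.28, Hes5 6.96 against 7.20, Aspa 8.95 against 7.67, Kif11 5.46 against 4.94 and the neural stem list 7.38 against 7.11. Among other controls, Kit was 6.58 against 7.70 in replicate 1, Ccnd1 7.41 against 7.68 in replicate 2 and Zeb1 9.26 against 9.63 in replicate 3.

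A set of genes changed in opposite directions in 2 tumour types against normal brain, and the direct difference passed limma. Sycp1 was lower in PDGF-p53 and higher in p53-RBPJ tumours, with a direct difference of 3.17, and Pcgf6 went the same way with 0.83. Sycp1 values were low, at 2.77 to 3.01 in PDGF-p53 arrays and 3.3, 3.67, 3.87 and 5.69 in controls. Control replicate 4, at 5.69, thus widened its fall in PDGF-p53 tumours. Chrdl1, Elovl5, Lrrtm3, Oxr1, S100a1 and Tpm1 were higher in PDGF-p53 and lower in p53-RBPJ tumours, with differences of -1.35, -1.16, -1.12, -1.44, -1.65 and -1.43. Between p53-RBPJ and PDGF-p53-RBPJ tumours, Chrdl1, Kcna6, Lrrtm3, Peak1, Rab3b and Tpm1 differed by -1.65, -0.93, -1.09, -1.48, -1.61 and -1.33, and Mgst1 by 1.76. Snora73b was lower in PDGF-p53 tumours and higher in both others, with differences of 1.36 for PDGF-p53-RBPJ and 1.34 for p53-RBPJ. Its fall in PDGF-p53 tumours was small, at -0.46 (limma adjusted p = 0.0481), with overlapping arrays.

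List medians differed between tumour types by camera, and none of these calls held with an estimated correlation. Between both PDGF types they were -0.18 for cholesterol, -0.33 for interferon, -0.28 for lymphocyte, 0.15 for mesenchymal, -0.19 for neural stem, -0.19 for neuron and 0.26 for proliferation genes. For p53-RBPJ against PDGF-p53-RBPJ they were -0.29 for astrocyte, -0.67 for cholesterol, -0.27 for hypoxia, -0.33 for immediate early, -0.38 for mesenchymal, -0.50 for microglia, -0.64 for neuron and -0.35 for oligodendrocyte genes. For p53-RBPJ against PDGF-p53 they were -0.39 for astrocyte, -0.98 for cholesterol, -0.35 for hypoxia, -0.51 for microglia, -0.83 for neuron, -0.34 for oligodendrocyte, -0.14 for precursor and 0.29 for proliferation genes.

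Probe sets without a single gene symbol, which the comparisons above left out, also changed. Of 13767, limma called 1964, 2207 and 3065 in PDGF-p53, PDGF-p53-RBPJ and p53-RBPJ tumours against normal brain. It called 58 between p53-RBPJ and PDGF-p53-RBPJ and 192 between p53-RBPJ and PDGF-p53 tumours.

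Other splits of the arrays were set beside each count of changed genes. By shares not adjusted for the number of tests, chance was argued against, though not excluded, for all 3 tumour types against control. These were PDGF-p53 (6208 genes, highest other split 26), PDGF-p53-RBPJ (6702, highest other 1) and p53-RBPJ (7330, highest other 2). In each, 1 of 35 splits, the real one, gave as many, and its share of 0.0286 is the smallest possible. The other splits mix both groups, so a real difference enters their spread and lowers their counts. The size of the gap therefore says little, and only the rank of the real split bears on chance. The same held for p53-RBPJ against PDGF-p53-RBPJ (651, highest other 9) and against PDGF-p53 (1105, highest other 4), and for the genes shared by all 3 types (4836, highest other 0, 1 of 100 splits). Chance could not be excluded for PDGF-p53-RBPJ against PDGF-p53 (4 genes, highest other 6), where 2 of 35 splits gave as many.

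The 651 genes that differed between p53-RBPJ and PDGF-p53-RBPJ tumours were weighed against sex and host tissue. A sex difference of the size seen in normal brain was argued against, since female minus male among the controls, signed by the call, had a median of 0.048 and an upper quartile of 0.156, against a median call of 0.83. An additive effect of sex shared by all groups was argued against as the whole cause. With that term the median was 0.78 with a lower quartile of 0.59, and 651 of 651 kept their sign. The median SE rose from 0.183 to 0.221. Whether calls were lost through the larger SE or the smaller folds was not tested. Sex acting only in tumours, PDGF-B and the route of induction remain open, untested. Less normal brain in the p53-RBPJ samples was argued against for 27.3% of the calls (178 of 651), which ran opposite to normal brain. For the 197 that ran with it, less normal brain and a change in the tumour cells cannot be told apart, because the design holds no purity measure. All 3 lists of normal brain cell types fell by camera, with medians of -0.64 for neuron, -0.35 for oligodendrocyte and -0.29 for astrocyte genes. None of these list calls held with an estimated correlation. The other 276 were not called between PDGF-p53 tumours and normal brain, so this test decided nothing for them.

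Of these lists, none of the 30 neuron or 17 oligodendrocyte genes and 2 of the 19 astrocyte genes stood in another list. The most abundant neuron gene, Snap25, averaged 12.66 in control, 10.15 in PDGF-p53, 9.98 in PDGF-p53-RBPJ and 8.93 in p53-RBPJ arrays. The myelin gene Mobp averaged 11.15, 8.70, 8.49 and 7.21, and the astrocyte gene Aldoc 12.17, 10.65, 10.16 and 10.37.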

How the results depend on the processing

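The tests with a sex term were chosen only after the results were seen. Counts against normal brain stayed within 1.5 times in every setting run. Leaving out 1 array gave 5262 to 6287 genes for PDGF-p53, 5851 to 6758 for PDGF-p53-RBPJ, 6728 to 7403 for p53-RBPJ and 4296 to 4898 for all 3 types, and the other settings gave 5759 to 8278, 6071 to 9071, 6422 to 10784 and 4524 to 6366. For p53-RBPJ against PDGF-p53 (1105 genes), only the 2 groups in the fit gave 289, a sex term 183 and leaving out 1 array 553 to 1323. For p53-RBPJ against PDGF-p53-RBPJ (651 genes), every probe set gave 351, array weights 1198, only the 2 groups 395, a sex term 61, of which 60 were shared, and leaving out 1 array 176 to 806. For PDGF-p53-RBPJ against PDGF-p53 (4 genes), every probe set, housekeeping centring and a replicate block each gave 2, and leaving out 1 array 2 to 7. The cause was not tested in any of these settings. With the sex term the median SE of the 651 genes rose, and their median fold change fell from 0.83 to 0.78. Housekeeping centring moved the share of higher calls from 19.5% to 61.5% and from 34.8% to 72.6% between p53-RBPJ and the PDGF types, where the median of all genes was 0.142 and 0.156. In the same setting that median was -0.125 for PDGF-p53 and -0.116 for PDGF-p53-RBPJ against normal brain.

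Among the lists called by camera, 3 medians turned in sign in some setting. Between both PDGF types the cholesterol median (-0.18) was 0.006 with array weights and 0.005 without PDGF-p53-RBPJ replicate 4, and the interferon median (-0.33) was 0.053 without PDGF-p53 replicate 4. The precursor median for p53-RBPJ against PDGF-p53 (-0.14) was 0.007 with housekeeping centring (camera adjusted p = 0.00666). The neuron list between both PDGF types (-0.19) ranged from -0.297 without PDGF-p53-RBPJ replicate 3 to -0.01 without PDGF-p53 replicate 3, where camera's direction turned. The oligodendrocyte list there (0.00, camera adjusted p = 0.778) ranged from -0.161 without PDGF-p53 replicate 2 to 0.226 without PDGF-p53 replicate 3 (adjusted p = 0.0205). Pdgfa in p53-RBPJ tumours against normal brain (0.56, adjusted p = 0.462) was -0.33 without p53-RBPJ replicate 1 (adjusted p = 0.047) and 0.92 without replicate 3. With an estimated correlation 47 list calls over the 6 comparisons were lost and with fry 28. Over all genes named by the rule, calls were lost 87 times with a sex term, 65 with only the 2 groups, 60 with every probe set, 24 with housekeeping centring, 24 with trend and robust, 20 with array weights, 18 with cyclic loess, 14 with a replicate block, 7 with median centring and 3 with the mean of probe sets.

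The replicate numbers are not stated to pair arrays. Same-numbered arrays deviated together with correlations of -0.121 to 0.182 over 24 pairs, of which 7 exceeded 0.1, and 11 matched their own number best. With a replicate block the counts were 6232, 6641 and 7321 against normal brain, 2 between both PDGF types, and 682 and 1150 for p53-RBPJ against PDGF-p53-RBPJ and PDGF-p53.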

Other observations

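All tests on neighbouring genes were chosen only after the results were seen.

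Abcb1a, the P-glycoprotein efflux pump, fell by 1.39 ± 0.15, 1.34 ± 0.15 and 1.39 ± 0.15 in PDGF-p53, PDGF-p53-RBPJ and p53-RBPJ tumours against normal brain (adjusted p = 1.24e-06, 1.44e-06 and 6.52e-07). Slco1a4, an organic anion carrier, fell by 2.07, 2.59 and 2 (log2, SE 0.31 each). The endothelial list did not pass camera in any of the 3 (adjusted p = 0.378, 0.432 and 0.098), with 5, 5 and 6 of 15 members lower over all genes and 5, 6 and 6 adjusted over the list alone, and 1 higher in p53-RBPJ tumours by both counts.

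Postn, a secreted matrix protein, rose by 3.54 ± 0.47, 3.10 ± 0.47 and 2.38 ± 0.47 in the same order (adjusted p = 1.43e-05, 4.79e-05 and 0.000507), while the matrix list did not pass (camera adjusted p = 0.371, 0.388 and 0.948). The transcription factor Zeb1 rose by 1.44 ± 0.20 and 1.12 ± 0.20 in the PDGF types and fell by 1.49 ± 0.20 from PDGF-p53 to p53-RBPJ tumours (adjusted p = 0.000583). Among p53 targets, Gtse1, a microtubule protein of the G2 phase, rose by 0.86, 0.79 and 0.95 (SE 0.13 each), and Perp, a membrane protein of apoptosis and adhesion, fell by 0.91, 0.70 and 0.75 (p53-RBPJ minus control, p53 targets list, adjusted p = 0.00014). The p53-RBPJ value of Perp lay outside the naming rule, so the alternatives were not run on it. The p53 target list did not pass in any of the 3 (camera adjusted p = 0.847, 0.968 and 0.948).

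A gene's value in a tumour array was taken as its difference from the median of all other tumour arrays, p53-RBPJ arrays included. Each tumour array was scanned along the gene order of assembly GRCm38.p6 for neighbouring genes that were high or low together, over 18562 protein-coding genes in windows of 7, with settings chosen after a first look. It found 10 blocks of at least 10 genes with a median of at least 1 in size, of which 9 were in p53-RBPJ arrays. Most tumour arrays are PDGF tumours, so differences shared by p53-RBPJ tumours remain in the values of p53-RBPJ arrays. The numbers of blocks per group are therefore not on an equal footing. Both patterns weighed here were picked from the 10 afterwards, and their tests were narrowed from all blocks to these once results were known. Of the others, the block from Usp46 to Tmem165 in p53-RBPJ replicate 1, which also holds Kit and Pdgfra, had a median of 1.01. Genes not used to find that block had 0.28, against 0.85 for those used. The block from Aim2 to Olfr433 in PDGF-p53 replicate 4 (1.23) was found by 0 scans of alternate genes, and it and the block from Col11a2 to H2-Eb2 in p53-RBPJ replicate 2 (1.09) lay at percentiles of 98.9 and 99 for correlation in the PDGF tumours. The rest were in p53-RBPJ replicate 1, from Map11 to Dnaaf5 (1.10), Fbn2 to Dctn4 (-1.32) and Armcx5 to Kir3dl2 (-1.16). In that order, the genes not used to find them had medians of 1.22, -0.94 and -1.87, and the correlation percentiles were 44.7, 49.1 and 70.6. The block from Map11 to Dnaaf5 holds Pdgfa, which was 3.51 above the median of all other tumour arrays.

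In p53-RBPJ replicates 3 and 4, 34 neighbouring genes from Sox5 to Resf1 had medians of 3.12 and 1.76 above the median of all other tumour arrays. Chance placement was argued against, since the highest window in 100 shuffles of the gene order reached 0.96. Regulation that also runs in the PDGF tumours was argued against, since the genes' correlation there lay at a percentile of 74.5 among random windows, while regulation particular to these tumours was not tested. A local gain of DNA is a hypothesis that stays open, and the genes not used to find the block had a median of at least 1.35. DNA was not analysed here.

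Kit lay in blocks of 22 genes from Rasl11b to Arl9 in p53-RBPJ replicate 2 (median 2.21) and of 13 genes from Gsx2 to Aasdh in replicate 4 (1.20). Chance placement was argued against by the same shuffles (highest 0.96). Regulation of the neighbours together that also runs in the PDGF tumours stays open, at a percentile of 96.9. A local gain stays open too, as a hypothesis without DNA data, with a median of at least 1.52 in the genes not used to find the blocks. Pdgfra lies in both blocks, and its values of 12.75 and 12.78 in these arrays compare with 13.03 in replicate 1 and 10.77 in replicate 3. In replicate 1 Pdgfra lay in the block from Usp46 to Tmem165, at 1.16 above the median of all other tumour arrays.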
